A study of Canis lupus familiaris with 20 samples.

How the data were processed

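Gene expression was measured in muscle of 10 dogs aged 2 years with canine Agilent arrays that carry 2 colours. The labels give the tissue as muscle without naming which muscle, and they place 4 dogs in the normal group, 4 in the affected group and 2 in the escaper group. Affected and escaper dogs both carry the label of Duchenne muscular dystrophy (DMD), a disease in which the muscle protein dystrophin is missing, and escapers are dystrophic dogs known for a mild course. Each dog was hybridised on 2 arrays against a common reference, once in Cy5 and once in Cy3, which gave 20 arrays. The reference was RNA of 1 individual labelled normal. Each of the 5 slides held the 4 arrays of 2 dogs from 1 group, so normal and affected dogs each lay on 2 slides and the escapers on 1. Slide and escaper group therefore cannot be told apart, and no slide holds 2 groups.

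Spots were scanned and quantified with Agilent Feature Extraction 9.5.3.1, per the file headers. The deposited files hold the mean intensity of each spot and the median intensity of its local background in red and green, per the file headers. They also hold processed intensities that had been corrected for background and spatial trends and dye-normalised by linear and LOWESS steps, per the file headers. The deposited value table holds log2 ratios, and its processing is not stated in the sources used here. Set against the scanner files, each column of the table equalled the log2 ratio of processed signals of dog over reference (r = 1), with arrays in swapped dye already turned. Scale and direction of the table are thereby settled, while the reason for leaving the columns uncentred stays unknown. Its column medians, given as dog in Cy5 and then dog in Cy3, were 0.01 and 0.21 in normal 1, −0.16 and 0.18 in normal 2, −0.08 and 0.16 in normal 3, and −0.09 and 0.12 in normal 4. They were −0.07 and 0.09 in affected 1, 0.12 and 0.25 in affected 2, 0.00111 and 0.21 in affected 3, −0.04 and 0.19 in affected 4, 0.04 and 0.24 in escaper 1, and −0.06 and 0.13 in escaper 2. The table served as an alternative only.

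From the mean and background signals, each array was corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, fitted on all spots. Loess normalisation within each array gave control spots no weight. Control spots and spots with an outlier flag were then left out, and saturated spots were kept. Ratios were turned to dog over reference on every array. The 2 arrays of a dog were then averaged, so that the dog is the replicate and a dye effect cancels. Each array carries 43451 spots, of which 1417 are controls, and 42034 probes remain. A probe entered the tests if it was well above background in the dog's channel on both arrays of at least 2 dogs, which 16130 probes met. Of these, 16008 had an unflagged spot in every dog and were tested, a condition added once the files had been read because the fits need a value from each dog.

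Gene symbols came from the array files and were updated through a table of dog genes of assembly UU_Cfam_GSD_1.0, used for names only. A symbol was found for 12289 probes, standing for 10388 distinct symbols, of which 833 probes kept a symbol of the file that the table does not hold, and 29745 probes stayed unnamed. Among tested probes, 7307 had a symbol and stood for 6192 genes, each represented by its probe with the highest mean log2 intensity. Coordinates are those of the array files, and the sources used here do not name their genome build.

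All 10 dogs entered a single limma fit with 3 groups, and moderated statistics gave 3 comparisons with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. The 3 groups share an estimate of the spread because the escaper group holds 2 dogs. A total of 28 gene lists were written down, 10 of them markers of cell types, and lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, adjusted over all lists and the 3 comparisons. Camera with an estimated correlation and fry were run beside it, and the member counts are given over all probes and adjusted over the list alone. The ranked form of camera stood in for the slide block, for all arrays with the dog as a block, and for the trend and robust variance, since camera takes no block. The mean log2 ratio of a list in each dog gave a list score, compared between affected and normal dogs with a two-sided exact permutation test over 70 arrangements.

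Named genes followed a rule. In each comparison they are the genes with a symbol that passed with no overlap between dogs, up to 10 in each direction, or, where none passed in a direction, the 5 with the smallest p. The 4 members of each list with the smallest p among those that passed, or otherwise the 1 member with the smallest p, and 11 genes chosen for the disease were added. The groups, tests, lists, naming rule and the alternatives listed further on were chosen before the data were examined. Leaving out 2 dogs together and joining affected and escaper dogs were chosen afterwards. A probe not well above background on any array of a group has only a bound there. Its fold is the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal, in normalised log2 values, and is written as at least that many fold. It is taken in the dog's channel and not in the ratio to the reference.

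The fits were tested on simulated data with 200 of the 16008 probes changed. For affected against normal, 52% of probes changed by 1 on the log2 scale and 91% of those changed by 2 were recovered, and 11 unchanged probes were called. For escaper against normal the shares were 32% and 87%, with 4 unchanged probes called. Over 20 simulated draws of the lists for affected against normal on 6192 genes, 1 of 1440 tests without an effect was called, and a list shifted by 0.5 was called in 20 draws with a mean estimate of 0.52. Simulated values were drawn independently for each probe and dog, with the same spread of a probe in every dog. The simulation therefore does not cover genes that move together or dogs of unequal spread. Its shares are not error rates for these data. The number of dogs limits the precision.

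The alternatives covered no background correction, Agilent's processed signals, the deposited value table, a normexp offset of 10, median centring in place of loess, quantile normalisation between arrays, no filter on dim probes and a filter asking for both channels on all arrays (9817 probes). They also covered the slide as a random block (limma with statmod 1.5.0), all 20 arrays with the dog as a block and a dye term, each dye orientation alone, the 2 compared groups alone, a trended and robust variance, array weights, and each dog left out in turn. The slide block had a negative correlation, which narrows the SE of group means and can raise its counts. The series holds no sample outside the 3 groups, and nothing was aligned or requantified from images.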

Results

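Muscle RNA of 4 normal, 4 affected and 2 escaper dogs was measured against a common reference on 20 arrays, 2 with opposite dyes for each dog. On the arrays, 30.5% to 60.2% of the 42034 probes were well above background in the dog's channel, with median signal over background from 1.67 to 5.28 and 15 to 156 saturated probes. The highest share belonged to the Cy5 array of affected 4. Ratios of the 2 arrays of a dog correlated with r from 0.627 in affected 4 to 0.939 in escaper 2 over 16008 tested probes. Genes are not independent replicates, and the shared reference raises correlations between dogs.

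Normal dogs resembled each other, with r from 0.78 to 0.86 between pairs, while pairs of affected dogs ranged from −0.19 to 0.65 and the escaper pair had r = −0.01. Affected 1 had its highest r with any dog at −0.01. Escaper 2 had its highest r, 0.42, with affected 4, and escaper 1 had its highest r, 0.76, with affected 2. The first 3 principal components held 47.1%, 25.9% and 9.12% of the variance. Escaper 2 had the highest score on the first (98.9) and affected 1 on the second (85.4).

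**Figure D1:**
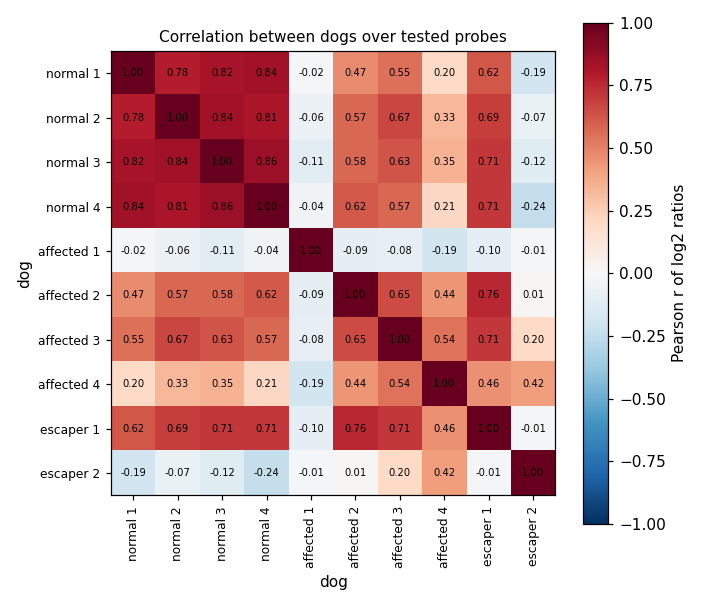
Pearson r of log2 ratios between the 10 dogs over the tested probes, with dogs on both axes, the value in each cell and colour from −1 to 1. The 4 normal dogs form a block between 0.78 and 0.86, while affected 1 lies between −0.19 and −0.01 with each other dog.

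DMD, the gene of dystrophin, did not differ past the threshold between the groups at its 1 probe (chromosome X, 27925343 to 27927065). Its log2 ratio to the reference was 0.04 ± 0.08 (SD, n = 4) in normal, 0.07 ± 0.30 (n = 4) in affected and −0.16 ± 0.21 (n = 2) in escaper dogs. The difference of affected and normal dogs was 0.03 on the log2 scale (SE 0.16, limma adjusted p = 0.954). The probe was well above background on 10 of 20 arrays and on none of an escaper. Escapers lay −0.21 from normal (adjusted p = 0.60) and −0.23 from affected dogs (adjusted p = 0.818) in the ratio. Without escaper 2 these were −0.06 and −0.08, so no minimum fold is given. The disease of these dogs is known to come from a splice-site change and not from loss of the whole gene, so this probe does not check the labels. UTRN, which encodes the dystrophin relative utrophin, was well above background on 0 of 20 arrays, the Notch ligand JAG1 on 1 and myostatin, MSTN, on 2, and these 3 genes were not tested. MYOG and MYH3 had no probe with that symbol.

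The comparison of affected with normal dogs asked how dystrophic muscle differs from healthy muscle. ROGDI, the gene mutated in Kohlschütter-Tönz syndrome, fell 4.93-fold in affected dogs (log2 change −2.30, SE 0.22, limma adjusted p = 0.0157), and all 4 affected dogs lay below all 4 normal dogs. Its level was 1.73 ± 0.46 (SD, n = 4) in normal and −0.57 ± 0.19 (n = 4) in affected dogs, at a probe on chromosome 6, 39666304 to 39666363. An unnamed probe on chromosome 5 at 36234161 to 36234220 rose 8.96-fold (log2 change 3.16, SE 0.37, adjusted p = 0.0391), from −2.90 ± 0.37 to 0.27 ± 0.76. A second unnamed probe on chromosome 5 at 84795185 to 84795244 fell 2.51-fold (log2 change −1.33, SE 0.13, adjusted p = 0.0157), from 0.71 ± 0.15 to −0.62 ± 0.11, and both unnamed probes were chosen after their values were seen. These 3 of 16008 probes, 1 up and 2 down, were all that passed, while 1986 (12.4%) had an unadjusted p under 0.05, where chance gives 800. At an adjusted p under 0.1, 18 probes passed, 6 up and 12 down. The escapers take no part in this difference, but their spread enters the shared estimate. With the 2 groups alone, 113 probes passed. Affected and normal dogs did not overlap in 829 of 6192 genes (13.4%), where chance gives 2.86%. ROGDI did not pass without normal 2 (adjusted p = 0.0692), affected 2 (0.0541) or affected 4 (0.0759), and ranged from 2.38e-07 to 0.0759 over its alternatives with log2 changes from −2.67 to −2.09. The count was 0 without normal 2, affected 2 or affected 4, 1 without normal 3 or normal 4, 6 without affected 3, 21 without affected 1, 113 without either escaper and 118 with the slide as a random block.

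No gene with a symbol passed upward in affected dogs. The 5 with the smallest p were LARP6, which binds collagen messenger RNAs (log2 change 1.83, SE 0.27, adjusted p = 0.0678), the annexin ANXA4 (1.22, adjusted p = 0.0883), the dynein chain DYNLRB2 (1.17, 0.109), the plakoglobin gene JUP (1.49, 0.109) and the imprinted RNA H19 (1.06, 0.119). In each of these genes all 4 affected dogs lay above all 4 normal dogs. Over the alternatives DYNLRB2 ran from 0.96 to 2.37. LARP6 was −2.33 ± 0.23 (SD, n = 4) in normal, −0.50 ± 0.11 (n = 4) in affected and −0.66 ± 1.01 (n = 2) in escaper dogs. Of the genes chosen for the disease, osteopontin, SPP1, had the largest difference (log2 change 3.77, SE 1.05, adjusted p = 0.258), with means of −7.55 ± 0.56 in normal and −3.78 ± 2.14 in affected dogs. The SPP1 probe was well above background on 16 of 20 arrays, so its difference rests partly on dim spots. COL1A1, a collagen I chain, was not well above background in normal dogs and was so on 2 of 8 arrays of affected dogs (limma adjusted p = 0.520). The mean of affected dogs was at least 1.19-fold higher, which is no minimum for each dog. COL1A1 ratios were 0.44 and 0.58 in affected 3 and 4, 0.01 and 0.04 in affected 1 and 2, and −0.17 to −0.03 in normal dogs. LTBP4 differed by 0.28 (adjusted p = 0.611) with its 2 probes opposite in sign, the macrophage gene CD68 by 0.19 (0.676) and the adipocyte gene ADIPOQ by 0.07 (0.890). Without affected 4, LTBP4 was at 0.17 and ADIPOQ at −0.05, without affected 1 LTBP4 was at 0.44, and without affected 2 CD68 was at 0.07.

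**Figure D2:**
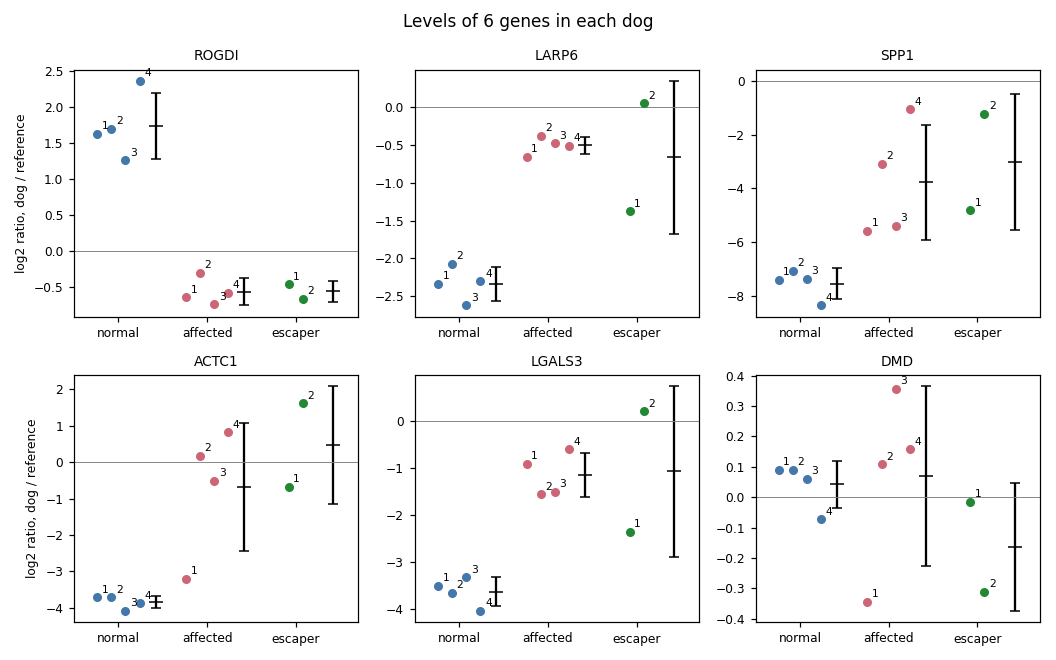
Log2 ratio of dog over reference for 6 genes, with 1 point for each dog, numbered by replicate, and a black bar for the mean ± SD of each group (4 normal, 4 affected and 2 escaper dogs). ROGDI lies above 1.25 in each normal dog and below −0.30 in each affected and escaper dog, while DMD varies within 0.36 of 0 in all dogs.

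Oxidative phosphorylation genes, which encode the respiratory chain, fell together in affected dogs (median log2 change −0.83, camera adjusted p = 2.5e-12, adjusted p = 0.626 with an estimated correlation). All 34 measured members were negative, 14 of them at an unadjusted p under 0.05, and 0 passed over all probes or adjusted over the list alone by limma. ATP5J, an ATP synthase subunit, had a log2 change of −1.16 (adjusted p = 0.264). Fatty acid oxidation and TCA cycle genes fell with a median of −0.66 and 21 of 22 negative (adjusted p = 6.7e-05, or 0.626 as p with an estimated correlation), with ACAT1, an enzyme of ketone and isoleucine breakdown, at −1.29. Without affected 1 their mean moved from −0.64 to −0.39. Glycolysis and glycogen genes fell with a median of −0.42 and 9 of 12 negative (adjusted p = 0.0358, or 0.626 as p with an estimated correlation), with muscle glycogen phosphorylase, PYGM, at −1.85. That call was lost without affected 1, when the mean moved from −0.57 to −0.36 (adjusted p = 0.194), and without normal 1 (mean −0.47, 0.0896). Without normal 2 (0.0506) or affected 4 (0.0566) it was lost with a mean no smaller, −0.58 and −0.60. Endothelial markers fell with a median of −0.20 and 8 of 9 negative (adjusted p = 0.0289, or 0.626 as p with an estimated correlation), and the VEGF receptor KDR, at −1.0, was the 1 member that fell adjusted over the list alone. The endothelial call was lost without normal 2 (0.0659), without affected 4 (0.0566) or with median centring (0.0739), with means about as large (−0.24, −0.23 and −0.25 after −0.27).

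Genes of regeneration and immature fibres rose in affected dogs (median log2 change 0.70, 9 of 10 positive, camera adjusted p = 0.00271, adjusted p = 0.626 with an estimated correlation). Of these, 3 rose adjusted over the list alone and 0 over all probes, where 4 had an unadjusted p under 0.05, and the foetal actin ACTC1 led with 3.16 (limma adjusted p = 0.229). The list score of affected 1, −1.60, lay among the normal dogs. Extracellular matrix genes rose with a median of 0.85 and 21 of 24 positive (adjusted p = 6.9e-04, or 0.626 as p with an estimated correlation), with COL5A2, a collagen V chain, at 1.88, and without affected 4 the mean moved from 0.81 to 0.53 and the call was lost (adjusted p = 0.0548). Macrophage and myeloid markers rose with a median of 0.71 and 18 of 20 positive (adjusted p = 5.9e-04, or 0.626 as p with an estimated correlation). Galectin 3, LGALS3, at 2.49, was the 1 member that rose adjusted over the list alone, and without affected 4 the mean of the markers moved from 0.87 to 0.57. All 11 ribosomal protein genes were positive with a median of 0.22 (adjusted p = 0.00609, or 0.626 as p with an estimated correlation), RPL3 was at 1.92 on a probe saturated on 2 arrays, and the call was lost without affected 3 with a mean about as large (0.37 after 0.39, adjusted p = 0.0518) and with median centring with a mean of 0.24 (0.273). Atrophy and autophagy genes, 12 of 13 positive, rose with a mean of 0.47 (adjusted p = 0.0289, or 0.690 as p with an estimated correlation), with the transcription factor FOXO1 at 1.17. This call rested on affected 1, without which the mean was 0.05 (adjusted p = 0.909) and FOXO1 was at 0.68, and it was lost with the mean unchanged without escaper 2 (0.0662) or with the slide as a random block (0.0520).

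With camera, 9 of 24 lists passed between affected and normal dogs, while other splits of the same 8 dogs gave up to 13. The other 15 lists had adjusted p from 0.0815 to 0.723. Their median log2 changes were 0.07 for the dystrophin complex, −0.44 for fast fibre genes, −0.05 for slow fibre genes, 0.27 for TGF-beta and myostatin signalling, 0.07 for the Notch pathway, −0.38 for calcium handling and 0.14 for the cell cycle. They were 0.26 for interferon response, 0.17 for antigen presentation and complement, −0.26 for immediate early and heat shock genes, 0.10 for T and NK cell, 0.45 for mast cell and granulocyte, −0.14 for adipocyte, −0.13 for smooth muscle and pericyte and −0.04 for skeletal muscle fibre markers. The means of slow fibre genes, 0.36, and T and NK cell markers, −0.32, had the opposite sign of their medians. The Notch pathway was listed because this disease model is known for it, so its direction is not independent evidence. Members with the smallest p in these lists included MYOZ2 (1.88), the syntrophin SNTB2 (1.15), MYBPC2 (−1.67), ATF3 (−2.09), the myoglobin gene MB (−1.86) and ADAM10 (0.48), and none of them passed. Too few genes were measured to test sex-linked (0), red blood cell (0), B and plasma cell (1) and Schwann and nerve (2) lists. JCHAIN, a plasma cell gene, differed by 0.21 and PMP22, a myelin gene, by 1.40, and neither passed. Without affected 1, PMP22 differed by 0.61 and MB by −1.01, and without affected 3 JCHAIN turned to −0.05. Among these 15 lists, slow fibre genes (mean 0.67) and interferon response (0.47) passed without affected 1, fast fibre genes (−0.93) and calcium handling (−0.57) without affected 3, and mast cell markers (0.45) without escaper 1. Fast fibre genes also passed without affected 2 (−0.76) and calcium handling without affected 4 (−0.54). List scores of affected and normal dogs did not overlap for oxidative phosphorylation, glycolysis and glycogen, ribosomal proteins and macrophage markers, each with the smallest p the exact permutation test allows, 0.0286, and 0.152 after adjustment over 24 lists.

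**Figure D3:**
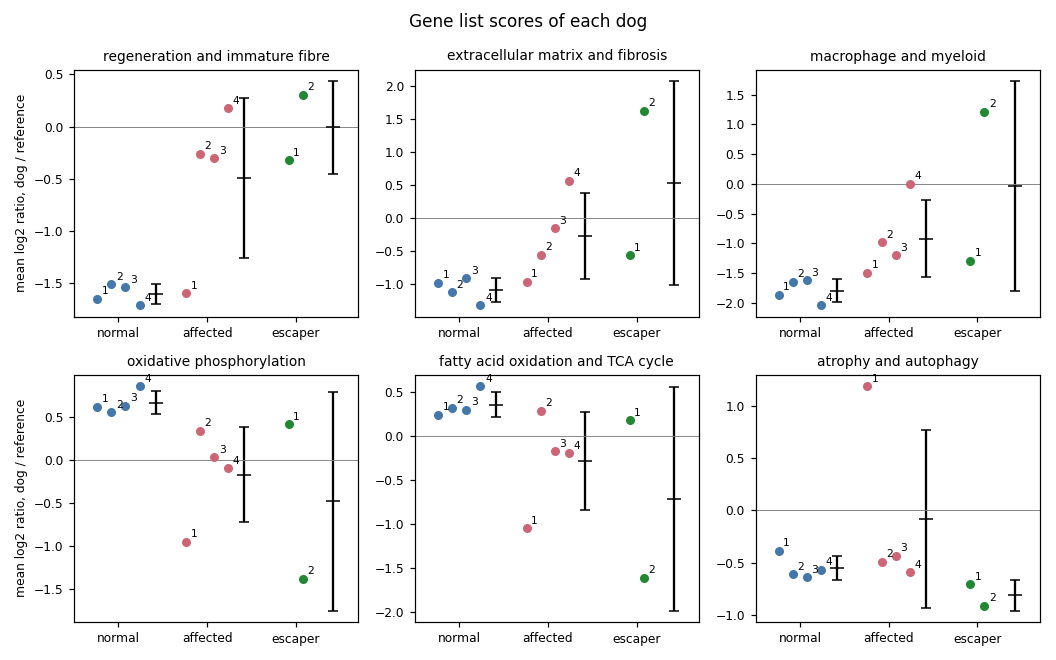
Mean log2 ratio of dog over reference of 6 gene lists, with 1 point for each dog, numbered by replicate, and a black bar for the mean ± SD of each group (4 normal, 4 affected and 2 escaper dogs). Escaper 2 has the highest macrophage score (1.22) and the lowest oxidative phosphorylation score (−1.38), and affected 1 has the highest atrophy score (1.19).

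Escapers were compared with normal dogs to ask what differs in muscle of dystrophic dogs with a mild course. No probe passed with limma, and 2947 of 16008 (18.4%) had an unadjusted p under 0.05, where chance gives 800. Among downward genes, ROGDI had the smallest p, with a log2 difference of −2.29 (SE 0.27, adjusted p = 0.0657), at −0.56 ± 0.14 (SD, n = 2) in escaper against 1.73 ± 0.46 (n = 4) in normal dogs. The mitochondrial ribosomal gene MRPL1 followed with −1.45 (adjusted p = 0.0657), and THAP4 (−1.93), the translation regulator CPEB4 (−1.20) and C37H2orf69 (−1.04) had an adjusted p of 0.182. Over the alternatives C37H2orf69 ran from −3.06 to −0.88. Upward genes were PLP2 with 1.10 (adjusted p = 0.0657), and TUBA1B, an alpha tubulin (2.98), the matricellular gene WISP2 (2.83), the actin-severing gelsolin gene GSN (1.85) and RAB32 (1.06), all with 0.182. The GSN probe was saturated on 10 arrays, that of TUBA1B on 2 and that of PLP2 on 1, so these 3 differences rest partly on saturated spots. Without escaper 2 the difference of THAP4 was −1.28. In each of these 10 genes both escapers lay outside the range of the normal dogs. SPP1 differed by 4.52 (adjusted p = 0.188) and was 2.72 without escaper 2. COL1A1 was not well above background in normal dogs (adjusted p = 0.334) and differed by 0.01 without escaper 2, so no minimum is given for both escapers. LTBP4 differed by 0.28 (0.586) and CD68 by 0.38 (0.364), which became −0.02 and 0.13 without escaper 2. ADIPOQ differed by 0.02 (0.971) and by −0.05 without normal 2. Groups did not overlap in 1911 of 6192 genes (30.9%), where chance gives 13.3%. The count was 3928 without escaper 1, when escaper 2 stands alone and is assumed to vary like the other groups, 3 without escaper 2, 10 without affected 1 and 517 with the slide as a random block.

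Macrophage and myeloid markers rose in escapers against normal dogs with a median of 1.53 and 20 of 20 positive (camera adjusted p = 7.5e-09, adjusted p = 0.626 with an estimated correlation). Of the markers, 11 rose adjusted over the list alone, among them LGALS3 (2.56), and 0 passed over all probes, where 15 had an unadjusted p under 0.05 by limma. Extracellular matrix genes rose with a median of 1.70, 23 of 24 positive and 7 up adjusted over the list alone (adjusted p = 1.2e-07, or 0.626 as p with an estimated correlation), with SPARC at 2.31 on a probe saturated on 4 arrays. Regeneration and immature fibre genes rose with a median of 0.91, 8 of 10 positive and 4 up adjusted over the list alone (adjusted p = 0.00271, or 0.626 as p with an estimated correlation), with the foetal troponin gene TNNT2 at 3.82. Ribosomal protein genes rose with a median of 0.41, 10 of 11 positive and 3 up adjusted over the list alone (adjusted p = 2.5e-04, or 0.626 as p with an estimated correlation), with RPS9 at 0.85 on a probe saturated on 3 arrays. Median centring in place of loess moved the median of all probes to −0.17 and the ribosomal mean from 0.63 to 0.03 (adjusted p = 0.642). Oxidative phosphorylation genes fell with a median of −1.24 and 34 of 34 negative (adjusted p = 4.1e-11, or 0.626 as p with an estimated correlation), with NDUFA5 at −1.56. Without escaper 2 these calls stayed, with the mean moved from 1.76 to 0.51 for macrophage markers, 1.62 to 0.52 for matrix, 0.63 to 0.33 for ribosomal and −1.15 to −0.25 for oxidative phosphorylation genes. Without escaper 1 the same means were 3.01, 2.72, 0.93 and −2.05. Without escaper 2, LGALS3 was at 1.28 and NDUFA5 at −0.74.

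A further 6 lists passed in escapers against normal dogs, each with an adjusted p of 0.626 with an estimated correlation, and each lost its call without escaper 2. Interferon response genes rose with a median of 0.93 and 11 of 11 positive (camera adjusted p = 9.1e-04), with IFI6 at 2.35, and had a mean of 0.27 without escaper 2 (adjusted p = 0.245) against 1.94 without escaper 1. Antigen presentation and complement genes rose with a median of 1.18 and 10 of 11 positive (0.00158), with CFD at 1.55, and had a mean of 0.23 without escaper 2 (0.428) and 2.23 without escaper 1. TGF-beta and myostatin signalling genes rose with a median of 0.59 and 9 of 12 positive (0.0422), with BMP4 at 1.22, and had a mean of −0.01 without escaper 2 (0.863) and 0.99 without escaper 1. That call was also lost without normal 4 (mean 0.44 after 0.49, 0.0710) and, with the mean unchanged, without affected 2 (0.0502) or with the slide as a random block (0.0520). With median centring the mean was 0.24 and the call stayed. Fatty acid oxidation and TCA cycle genes fell with a median of −1.18 and 22 of 22 negative (3.3e-06), with ETFDH at −1.57, and had a mean of −0.18 without escaper 2 (0.298) and −1.98 without escaper 1. Glycolysis and glycogen genes fell with a median of −0.83 and 11 of 12 negative (0.00247), with PHKG1 at −1.22, and had a mean of −0.19 without escaper 2 (0.42) and −1.86 without escaper 1. Skeletal muscle fibre markers fell with a median of −0.90 and 11 of 12 negative (0.0334), with MYPN at −1.52, and had a mean of 0.28 without escaper 2 (0.169) and −1.93 without escaper 1. The other 13 lists had adjusted p from 0.0579 to 0.947, with CCL5, a T and NK cell gene, at least 2.37-fold and the mast cell gene CPA3 at least 1.65-fold higher in escapers, neither passing by limma (adjusted p = 0.244 and 0.267). Both rested on escaper 2, without which the log2 differences fell from 1.28 to 0.18 and from 0.76 to 0.15. Without it IFI6 was at 0.87, CFD at 0.47, BMP4 at 0.50, ETFDH at −0.60, PHKG1 at −0.45 and MYPN at −0.16. Without escaper 2, slow fibre genes passed upward (mean 0.94) and immediate early and heat shock genes downward (−0.90), opposite to their means with both escapers, −0.20 and 0.46. Without escaper 1, immediate early (1.81), mast cell (2.54), endothelial (0.77), cell cycle (0.76) and calcium handling lists (−1.51) passed, the last also without normal 2, affected 1 or affected 3. The mast cell and granulocyte list has 4 measured genes and rests in escaper 2 largely on the chemokine gene CXCL8. CXCL8 was at 5.43 in escaper 2 and −2.68 to −1.49 in normal dogs, while in escaper 2 CPA3 was at 1.39 and S100A9 at 0.32. The dystrophin complex had a median of −0.15 and a mean of 0.10, and adipocyte markers had 0.02 and −0.13.

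Escapers were compared with affected dogs to ask what sets mild disease apart from the usual course. No probe passed with limma, the smallest adjusted p was 0.800, and 834 of 16008 probes (5.21%) had an unadjusted p under 0.05, where chance gives 800. The genes with the smallest p upward were the cytokine IL15 (log2 difference 1.27, SE 0.22, adjusted p = 0.800), GRIP2 (0.97), C4BPB (0.98), the smooth muscle actin ACTG2 (1.57) and TPST2 (0.87). Downward they were MRPL1 (−0.85), UCHL3 (−1.08), CPEB4 (−0.78), DCUN1D2 (−1.02) and HUS1 (−0.77), and both escapers lay outside the affected range in all 10. Without escaper 2, DCUN1D2 was at −0.63 and HUS1 at −0.46. IL15 was 0.99 ± 0.11 (SD, n = 2) in escaper, −0.28 ± 0.35 (n = 4) in affected and −0.16 ± 0.18 (n = 4) in normal dogs. SPP1 differed by 0.75 (adjusted p = 0.911) and COL1A1 by 0.14 (0.924), which turned to −1.05 and −0.35 without escaper 2. CD68 differed by 0.19 (0.860) and LTBP4 by 0.000793 (0.9997), which turned to −0.06 and −0.30 without escaper 2. ADIPOQ differed by −0.05 (0.971) and by 0.07 without affected 4. Groups did not overlap in 502 of 6192 genes (8.11%), where chance gives 13.3%. Without escaper 1 the count was 1747, and without escaper 2 it was 3, with the remaining escaper assumed to vary like the other groups.

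With camera, 13 lists passed between escaper and affected dogs, and all were lost with an estimated correlation (adjusted p from 0.626 to 0.783). Higher in escapers were macrophage and myeloid markers (mean 0.88, 20 of 20 positive, camera adjusted p = 2.2e-06), extracellular matrix (0.81, 23 of 24, 1.7e-05), antigen presentation and complement (0.85, 10 of 11, 2.0e-04), interferon response (0.77, 11 of 11, 3.6e-04) and immediate early and heat shock genes (0.66, 11 of 13, 0.00421). Without escaper 2 their means were −0.37, −0.29, −0.15, −0.06 and −0.69, and without escaper 1 they were 2.14, 1.91, 1.85, 1.61 and 2.01. Oxidative phosphorylation (mean −0.31, 33 of 34 negative, 0.0247), fatty acid oxidation and TCA cycle (−0.43, 21 of 22, 0.0113), glycolysis and glycogen (−0.45, 10 of 12, 0.0358) and skeletal muscle fibre genes (−0.60, 10 of 12, 0.0333) were lower. Without escaper 2 their means were 0.59, 0.47, 0.38 and 0.50, and without escaper 1 they were −1.21, −1.33, −1.29 and −1.70. These 4 calls were also lost without affected 2 or affected 3, and all but that of fatty acid oxidation without affected 4, with adjusted p from 0.0525 to 0.440. Their means without affected 2 were −0.14, −0.24, −0.35 and −0.38, and without affected 3 they were −0.24, −0.40, −0.36 and −0.58. For the calls lost without affected 4 the means stayed about as large. Without escaper 2 those of oxidative phosphorylation, fatty acid oxidation and skeletal muscle fibre genes passed in the opposite direction. Without affected 1, oxidative phosphorylation had a mean of −0.57 and fatty acid oxidation −0.69, and both passed. Endothelial markers were higher (mean 0.56, 8 of 9 positive, 6.7e-05), with KDR (1.02) in 1 member that rose adjusted over the list alone (0.59 without escaper 2), and had a mean of 0.08 without escaper 2 (adjusted p = 0.296) and 1.04 without escaper 1. Smooth muscle and pericyte markers were higher (mean 0.22, 6 of 8 positive, 0.0287), with TAGLN at 0.57 (0.21 without escaper 2), and that call was lost without either escaper (0.158 without escaper 1 and 0.110 without escaper 2), affected 1 (0.119) or affected 4 (0.0548), with means from 0.15 to 0.25. With median centring its mean was 0.04 and the call stayed. Ribosomal protein genes were higher with loess (mean 0.24, 10 of 11 positive, 0.0149) and lower with median centring (−0.21), which moved the median of all probes to −0.18, and had a mean of −0.06 without escaper 2 and 0.54 without escaper 1. The ribosomal call was also lost without affected 4 with a mean about as large (0.23, 0.0566).

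Atrophy and autophagy genes were lower in escaper than in affected dogs (mean −0.73, 13 of 13 negative, camera adjusted p = 2.0e-04, adjusted p = 0.626 with an estimated correlation). ULK1, a kinase that starts autophagy, was at −0.62 (limma adjusted p = 0.800). Without affected 1 the mean was −0.31 and the list still passed (adjusted p = 0.00577), and without affected 1 and escaper 2 together it was −0.20 and did not pass (0.0853). The escaper scores, −0.71 and −0.92, lay below those of all affected dogs, which were −0.59 to −0.44 in 3 dogs and 1.19 in affected 1. The 15 arrangements of 2 escapers and 4 affected dogs allow no exact p under 0.0667. The other 11 lists had adjusted p from 0.0640 to 0.846. Of these, slow fibre (mean 0.57), fast fibre (0.75) and adipocyte lists (0.26) passed as higher without escaper 2. Without escaper 1, slow fibre (−1.71) and calcium handling (−1.07) passed as lower and mast cell (2.08), TGF-beta (0.77) and cell cycle lists (0.66) as higher. Without affected 1, slow fibre (−0.87), calcium handling (−0.65), Notch (0.28) and cell cycle lists (0.37) passed, without affected 3 slow fibre genes (−0.71), and without affected 4 regeneration (0.71) and TGF-beta lists (0.35). The mast cell and granulocyte list has 4 measured genes, of which CXCL8 was at 5.43 in escaper 2 and −1.84 to −1.32 in affected dogs. With all dogs, fast fibre (median 0.06, mean −0.18) and adipocyte lists (median −0.05, mean 0.05) differed in sign between median and mean.

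Across 6192 genes, the difference of escaper from normal dogs and that of affected from normal dogs correlated with r = 0.763 and Spearman's rho = 0.683. Genes are not independent replicates, and both differences share the 4 normal dogs. Unchanged groups simulated against shared controls gave a mean r of 0.407 and a mean rho of 0.378 over 100 draws. These draws took genes as independent and the spread of a gene as equal in all dogs. They therefore do not show how far r or the covariance may range by chance in these data. With the normal dogs split into 2 pairs, 1 for each difference, r was 0.631 to 0.710 over the 6 ways and 0.684 on average. The covariance was 0.230, against 0.0427 in the simulation, and 0.197 to 0.226 over the splits.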

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

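The tests on affected 1 and escaper 2 were chosen only after the result was seen, and those on the reference were set before it. The test of fibre loss replaced an earlier one on list means, which had argued against it in both dogs but took no account of members that went both ways. In groups of 4 dogs, the gap between the most distant dog and the nearest of the others was divided by the group's whole range, and chance alone puts about 1 in 20 groups above the critical value. Of 228 groups tested, 15 lay above it, 8 of them through affected 1, 6 through a normal dog and 1 through another affected dog.

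Affected 1 stood apart from the other 3 affected dogs in its list scores of the dystrophin complex (−0.56 against 0.03 to 0.07, gap over range 0.935), calcium handling (−1.24 against 0.10 to 0.20, 0.930), atrophy and autophagy (1.19 against −0.59 to −0.44, 0.912) and T and NK cell markers (−1.06 against −0.03 to 0.12, 0.874). It also stood apart in ACAT1 (−1.70 against −0.41 to −0.15, 0.834), MCM7, a DNA replication gene (0.49 against −0.23 to −0.19, 0.946), SPARC (−2.11 against −0.17 to 0.21, 0.840) and the autophagy gene MAP1LC3B (1.30 against −0.38 to −0.21, 0.895). A failed array or a dye effect is argued against by its 2 arrays, which correlated with r = 0.872 where the lowest other pair had 0.627, and a swap with a normal dog by its highest r with a normal dog, −0.0215, where pairs of normal dogs had at least 0.78. A loss of fibres with a gain of all other cell types stays open by its test. That test asks whether lists differ from each other, so lists that all stay flat or fall together do not count against it. Among 4 marker lists with at least 5 genes, 0 lay below the highest by more than the joint SD of their genes. The predicted rise beyond the SD of the genes in every list was not met either. Median differences from the mean of the other affected dogs were −0.70 for macrophage, −0.49 for adipocyte, −0.07 for smooth muscle and 0.0078 for endothelial genes. Each lay within the SD of its genes, and 17 of 20 macrophage genes lay below that mean. A sample from outside the groups and another state of the muscle stay open too, and neither was tested.

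Escaper 2 differed from escaper 1 in macrophage (1.22 against −1.29), extracellular matrix (1.63 against −0.57) and oxidative phosphorylation scores (−1.38 against 0.42). A failed array or a dye effect is argued against by the r of its 2 arrays, 0.939, against 0.627 in the lowest other pair. Fewer fibres with all other cell types raised alike is argued against as the whole cause by 3 of 4 marker lists with at least 5 genes, which lay below the macrophage median of 2.56 by more than the joint SD of their genes. Endothelial genes had a median of 0.86 (1.70 below, joint SD 1.43), smooth muscle 0.33 and adipocyte genes −0.40, the last 2 with members both ways. The test assumes that muscle fibres express none of these list members, which was not checked. A change in macrophages stays open, as does a difference between the 2 dogs in disease, which was not tested.

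The reference RNA, labelled normal, lay more than 2-fold above every normal dog in 180 genes and more than 2-fold below in 46. SPP1 led at 7.55 ± 0.56 on the log2 scale (SD, n = 4), with the metallothionein gene MT2A (4.70), the neonatal myosin gene MYH8 (3.99), ACTC1 (3.84), LGALS3 (3.62), TIMP1 (3.29) and the foetal acetylcholine receptor gene CHRNG (2.67). In the dog's channel the SPP1 probe was well above background on 16 of 20 arrays. As a test of a dye effect, 100% of the 180 genes were higher in the reference in the mean over normal dogs of each dye orientation. The genes were picked from averages over both orientations, in which a dye effect cancels. That choice largely set the result of the test, so no conclusion is drawn from it. On single arrays of normal dogs SPP1 was below the reference on 8, TIMP1 on 7 and MYH8 on 6. A spot with an outlier flag was left out and cannot count here as below. Averaged over its arrays, each of the 4 normal dogs lay below the reference in these genes. That the reference is RNA of 1 of these normal dogs is argued against by the 450 genes in which the closest, normal 3, differed over 2-fold from it, where the next had 476. The state of the reference muscle stays open, and since every dog was set against the same RNA it cancels between groups.

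Among normal dogs, normal 4 lay lowest in H19 (−3.09 against −2.47 to −2.38, gap over range 0.874) and COL5A2 (−2.86 against −2.09 to −1.98, 0.881). Normal 1 lay lowest in the calreticulin gene CALR (−1.46 against −1.03 to −1.02, 0.983) and IFI6 (−2.49 against −1.71 to −1.63, 0.907). Normal 2 lay lowest in MYOM2 (−0.07 against 0.26 to 0.31, 0.869), and normal 3 lay highest in CPA3 (0.21 against −0.08 to −0.03, 0.844). With about 1 in 20 groups flagged by chance alone, these 6 flags of normal dogs may be chance. Affected 4 had a median signal over background of 3.75, averaged over its arrays, against 1.93 to 2.23 in the other affected dogs (gap over range 0.834).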

How the results depend on the processing

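The tests that leave out affected 1 and escaper 2 together were chosen only after the result was seen. No paired analysis was possible because the dogs of different groups share no number in the labels. The count of 3 probes for affected against normal became 19 without background correction, 31 with Agilent's processed signals or the deposited table, 22 with quantile normalisation, 118 with the slide as a random block, 337 with all arrays, 9 with the dog in Cy5 only, 1 in Cy3 only, 113 with the 2 groups alone, 578 with array weights and 899 without both dogs. It was 18 at an adjusted p under 0.1, 1 over genes with a symbol, and 0 (normal 2, affected 2 or affected 4 left out) to 113 (either escaper left out) without single dogs. The escaper against normal count of 0 became 4 with processed signals or the deposited table, 3 with quantile normalisation, 1 with no filter on dim probes, 517 with the slide as a block, 993 with all arrays, 20 without both dogs, 4 at 0.1, 3 over genes with a symbol, and 0 to 3928 (escaper 1 left out) without single dogs. The escaper against affected count of 0 became 8 without both dogs and 0 to 1747 (escaper 1 left out) without single dogs. By limma, 2947 and 834 probes had an unadjusted p under 0.05 in these last comparisons. The slide block had a correlation of −0.271, and the dog over its arrays 0.654. A negative slide correlation treats dogs of a slide as less alike than dogs of different slides and so narrows the SE of group means. The slide-block counts of 118 and 517 may therefore be too high. Array weights were 0.204 for affected 1 and 0.314 for each escaper. Leaving out an escaper changes only the shared spread for affected against normal dogs, so that count equals the count of the 2 groups alone. The same holds for the part of escaper 2 in the count without both dogs.

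The 33 list calls over the 3 comparisons became 21 without both dogs, 0 with an estimated correlation and 0 with fry, and ranged from 22 (escaper 2 left out) to 43 (escaper 1 left out). Of the 33, 21 were lost without both dogs, 19 without escaper 2, 8 without affected 4 and 0 to 5 without any other single dog. With other choices 10 were lost with the filter on both channels of all arrays, 5 with the dog in Cy3 only, 4 each with Cy5 only, median centring and array weights, 2 each with processed signals, the deposited table, the slide as a block, the 2 groups alone and the mean over probes of a gene, and 1 each with quantile normalisation and no filter on dim probes. None was lost without background correction, with an offset of 10, with all arrays or with a trended and robust variance. Escaper against normal means, over single dogs left out, ran from −1.35 to 0.94 for slow fibre, −0.90 to 1.81 for immediate early and heat shock and −1.93 to 0.28 for skeletal muscle fibre genes, and were 0.94, −0.90 and 0.28 without both dogs. Escaper against affected means ran from −1.71 to 0.57 for slow fibre, −0.29 to 1.91 for matrix, −1.21 to 0.59 for oxidative phosphorylation, −1.29 to 0.38 for glycolysis, −1.33 to 0.47 for fatty acid oxidation, −0.0633 to 1.61 for interferon, −0.15 to 1.85 for antigen presentation, −0.69 to 2.01 for immediate early, −0.37 to 2.14 for macrophage and −1.70 to 0.50 for skeletal muscle fibre lists. In each range escaper 1 or escaper 2 was the dog left out at either end. Without both dogs the escaper against affected means were −0.52 for matrix, 0.33 for oxidative phosphorylation, 0.17 for glycolysis, 0.21 for fatty acid oxidation, −0.20 for interferon, −0.39 for antigen presentation, −0.79 for immediate early, −0.0599 for ribosomal, −0.56 for macrophage, 0.21 for skeletal muscle fibre and −0.20 for atrophy and autophagy lists. The ribosomal list also turned to −0.21 with median centring, which moved the median of all probes to −0.17 for escaper against normal and −0.18 for escaper against affected. The relation of the differences of escaper and affected dogs, r = 0.763, was 0.677 without both dogs, 0.684 on average over splits of the normal dogs, and 0.571 (escaper 2 left out) to 0.802 (affected 1 left out) without single dogs. Of 3238 values of named genes under alternatives, 2981 kept direction and side of the threshold, 185 newly passed, 3 no longer passed, 69 turned sign and passed neither before nor after. Of 2076 values of single lists, 1771 kept direction and call, 149 no longer passed, 65 newly passed, 64 turned sign and passed neither before nor after, and 27 turned sign and passed before, after or both. The cause was not tested for any of these, and median signal over background from 1.67 to 5.28 limits what dim probes can show. Among named genes only ROGDI, in affected against normal dogs, passed in the main fit. Keeping the side of the threshold therefore mostly means not passing again. Settings that alter only the variance leave the log2 change as it was, and the deposited table repeats the processed signals.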

Other observations

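The comparison of all dystrophic with normal dogs was added once the data had been examined, with its splits set before its own result, and the genes without affected 1 and escaper 2 were chosen only after the result was seen. Without those 2 dogs, 899 probes differed between 3 affected and 4 normal dogs, 434 up and 465 down. Genes of immature fibres included MYH8 (log2 change 4.07, SE 0.24, limma adjusted p = 6.8e-04), ACTC1 (4.00, 8.2e-04) and TNNT2 (2.34, 0.00466). Matrix genes included the collagens COL3A1 (2.86, 0.0215), COL1A2 (2.67, 0.0101) and COL5A2 (2.40, 0.0127), and SPP1 (4.38, 0.0251), LGALS3 (2.41, 0.00352) and DLA-DRA, a class II antigen presentation gene (2.79, 0.0326), also rose. Falling genes were ROGDI (−2.28, 0.00352), HSD11B1, which activates glucocorticoids (−2.12, 0.00389), the mitochondrial fission gene MTFP1 (−2.10, 0.00801), CES1 (−1.87, 0.0128) and the acyl-CoA synthetase gene ACSL6 (−1.67, 0.0309). Both dogs were left out for their values, so these p-values are too small.

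All 6 dystrophic dogs together differed from the 4 normal dogs in 18 probes, 7 up and 11 down, and 2862 probes (17.9%) had an unadjusted p under 0.05. The 6 that carry a symbol were ROGDI (log2 change −2.30, SE 0.19, limma adjusted p = 0.00264), LARP6 (1.78, 0.0290), ANXA4 (1.20, 0.0373), C37H2orf69 (−0.93, 0.0382), JUP (1.5, 0.0403) and ADK, the adenosine kinase gene (−0.95, 0.0422). In all 6 the dystrophic and normal dogs did not overlap. Of 100 splits drawn from the 210 possible into 6 and 4 dogs, 1 gave as many probes, the real one. The highest other gave 2, which argues against chance for this count.

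For affected against normal dogs, 1 of 35 splits into 4 and 4 gave as many probes as the 3 of the real one. The highest other gave 1, and a share under 0.05 had been set beforehand to argue against chance. A share of 1 in 35 meets this but is the smallest that 35 splits allow. The count was 0 without normal 2, affected 2 or affected 4, so chance is not firmly excluded. No slide held 2 groups, so the splits do not exclude an effect of the slides on this count or that of all dystrophic dogs. For gene lists, 18 of the 35 splits gave at least the 9 lists of the real one and the highest other gave 13, so chance cannot be excluded for the number of lists. Whether single lists exceed their own splits was not tested.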
